A study of Mus musculus with 12 samples.

How the data were processed

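The data were RNA-seq counts of 12 libraries from sorted splenic Treg cells of 4-week-old female mice, 4 libraries for each of 3 genotypes. Per the labels, cDNA was made with the SMART-Seq v4 low-input kit, and the library construction kit that followed is named differently in the series text and in the sample protocol. The authors deposited raw counts, the number of reads per gene and library without normalization. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 (GRCm38) with STAR 2.5.1b and counted per Gencode gene with HTSeq. The HTSeq version, the Gencode release and the strand setting are not given in the sources used here. The table held 25189 genes and 3 HTSeq summary counts per library (reads outside genes, ambiguous reads and reads without a unique alignment), which were used only as quality measures. The reads assigned to genes made up 62.3% ± 1.29 of the total in WT, 62.8% ± 1.89 in Foxp3-deficient and 60.5% ± 0.737 in double-deficient libraries (mean ± SD, n = 4). Gene positions, exonic lengths and GC content were taken from GENCODE M21 on GRCm38, to which 97.4% of the genes were matched (24077 by symbol and 452 by synonym).

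Libraries were grouped by the genotype that the labels give. Replicates are numbered 1, 3, 4 and 5 in WT and Foxp3-deficient and 2, 3, 4 and 5 in double-deficient cells, as the labels number them. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules, and the spread between libraries gave a biological coefficient of variation of 17.4%. No library was a copy of another. Genes were filtered with filterByExpr, which left 13196, scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, 1 fit over all 12 libraries without covariates). Log2 fold changes and standard errors come from that fit. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05. CPM were computed with TMM-scaled library sizes, and a prior count of 2 was used for log2 CPM in the principal component analysis. A ratio against a group with 1 to 3 reads is given with its 95% counting interval, and against a group with 0 reads as a bound with a floor of 3 reads over the group. Quality measures were compared by exact two-sided permutation tests, adjusted over 21 tests.

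The 3 comparisons, the tests, the rule for named genes and 29 gene lists were chosen before the data were examined. The lists were the Treg signature, naive and resting T cell, helper cytokines, the Th1, Th2, Th17 and Tfh programs, inhibitory receptors, cytotoxic granule and NK receptor, homing and chemokine receptors, TCR-induced, dissociation and heat shock stress, glycolysis, TCA cycle, OXPHOS nuclear, OXPHOS mitochondrial, ribosomal proteins, sterol and fatty acid synthesis, mTOR and PI3K-AKT components, proliferation, interferon response, apoptosis and survival, and markers of B cells, plasma cells, myeloid cells, dendritic cells, erythroid cells, platelets and NK and CD8 cells. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with the self-contained test fry as alternatives, and adjusted over the lists of a comparison. Named genes were, per comparison, Foxp3 and Rictor, up to 8 risen and 8 fallen genes with the largest fold change among called genes with a mean of at least 10 CPM and no overlap between the libraries of the groups compared (unnamed gene models, pseudogenes and receptor segments left out), up to 3 called members of each list with the smallest adjusted p, and from a list without called members the member with the highest mean CPM. Some genes are not reported here. Genes named outside that rule were chosen after their values were seen: in Foxp3-deficient against WT cells, Bank1, Batf, Bcl2l1, Ccr3, Ccr4, Ctla4, Fas, Foxo1, Gbp2, Gzmc, Ifit2, Igkc, Il21, Il2ra, Irf4, Lta, Ly6c1, Maf, Nrp1, Pdcd1, Plac8, Sh2d1a, Socs2 and Tnfsf11, in double-deficient against Foxp3-deficient cells, Batf, Bst2, Cd40lg, Cd74, Ctla4, Eif4ebp1, Emp1, Foxp1, Gata3, Gbp2, Hk1, Icos, Ikzf2, Il12rb2, Il1r1, Il2ra, Il7r, Isg20, Itga4, Itgae, Ldha, Ly6c1, Mdh1, Nrp1, Ogdh, Pde3b, Pfkm, Pfkp, Pik3r5, Pkm, Satb1, Sgk1, Tnfrsf9 and Wnt5b, in double-deficient against WT cells, Ccr4, Ctla4, Ctsw, Egr1, Egr2, Eno3, Fasl, Fgl2, Foxo1, Gbp3, Gbp4, Ifi27l2a, Ifit1, Ifit3, Il10, Il12rb1, Il21, Il2ra, Ldhb, Lta, Nfkbia, Nr4a2, Nr4a3, Nrp1, Pdcd1, Pkm, Ppp1r14c, Scd2, Sgk1, Slc2a1, Sqle, Stat2, Stat3, Tnfsf11, Tox2, Tpi1 and Zfr.

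Other settings were relative log expression and upper quartile scaling, no low-count filter, a stricter filter (at least 1 CPM in 4 libraries and a mean of 5 CPM), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were the removal of each library's trend with exonic length and GC content, alone and with the block, and leaving out Foxp3-deficient replicates 1 and 3 together. Genes called in a pair of comparisons that share a group were counted beside the overlap of independent lists, 20 simulations of unchanged groups and fits with the shared libraries split into pairs. The pipeline was tested on simulated data with 200 changed genes. At 1.5-fold it recovered 43.3%, 38.8% and 32.8% of them in the order of the comparisons, at 2-fold 61.2%, 68.7% and 76.1%, and at 4-fold 86.4%, 90.9% and 93.9%, with 10 false calls among 137, 8 among 140 and 9 among 144. With a length trend put into the second comparison, 197 false calls arose, and 7 remained after its removal. Exon-level reads, and so the deletion within Rictor, were not analysed here.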

Results

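RNA was sequenced from splenic regulatory T (Treg) cells, the CD4 T cells that restrain immune responses, of 4-week-old female mice. The 12 libraries fell into 3 groups of 4. WT cells carried a working Foxp3 gene marked by a red reporter, Foxp3-deficient cells carried a Foxp3 allele that drives a reporter and Cre recombinase in place of working Foxp3, and double-deficient cells had in addition lost Rictor, the subunit that defines mTOR complex 2. The cells were sorted as CD4-positive cells with a red or a yellow reporter, so that genotype and reporter went together as far as the labels tell. The labels do not say which mouse gave which library, so p-values measure the spread between these samples. Each library held between 15769737 and 26114044 reads assigned to genes. A group name followed by a number stands for that replicate. Of 25189 genes in the table, 13196 had enough reads to be tested. Values are the deposited counts scaled to a common library size (CPM), given as mean ± SD with n = 4 per group throughout.

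On a principal component analysis, component 1 (38.5% of the variance) put WT between −52.0 and −44.9, Foxp3-deficient between −10.5 and 22.9 and double-deficient libraries between 37.3 and 46.3, and component 2 took up 21.2%. The Foxp3-deficient libraries spread the most: replicate 1 stood at −59.4 on component 2 and replicate 3 at 55.2 on component 3. Several quality measures moved with the double-deficient group. Reads outside annotated genes made up 5.004% ± 0.366 there, against 7.83% ± 1.52 in Foxp3-deficient and 8.19% ± 0.507 in WT libraries, and reads without a unique alignment made up 32.2% ± 0.85, against 26.9% ± 2.80 and 27.0% ± 1.27. Both differences gave p = 0.0286 in an exact two-sided permutation test, the smallest value that 4 against 4 libraries allow, and 0.0751 after Benjamini-Hochberg adjustment over 21 such tests. Short transcripts were also higher in that group: across genes, the log2 fold change of double-deficient over Foxp3-deficient cells fell with exonic length (Spearman rho = −0.465, genes not being independent), from a median of 0.29 in the shortest of 5 length classes to −0.24 in the longest.

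**Figure D1:**
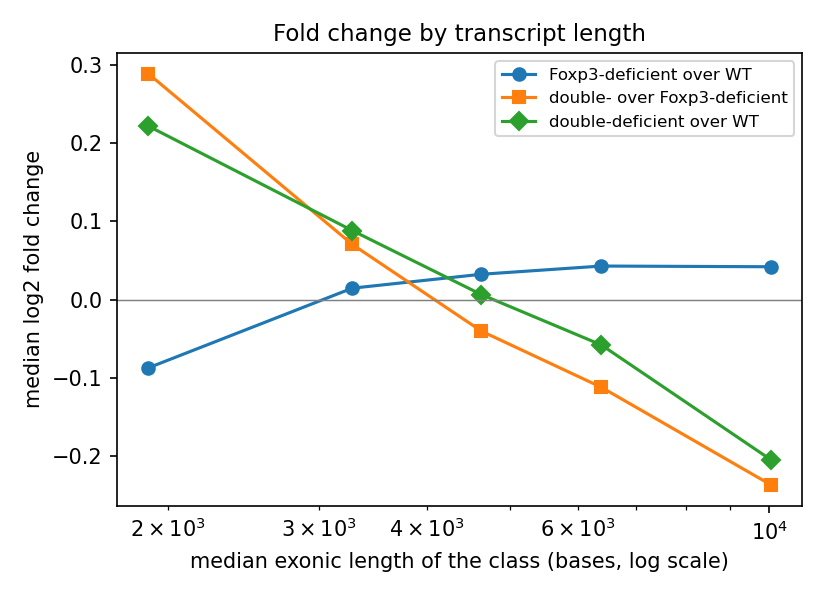
Median log2 fold change (y axis) of expressed genes in 5 classes of exonic length (x axis, median length in bases, log scale), 1 line per comparison. Double-deficient over Foxp3-deficient cells ran from 0.29 in the shortest to −0.24 in the longest class, and Foxp3-deficient over WT cells from −0.09 to 0.04.

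The targeted genes were read first. Foxp3, the transcription factor that defines Treg cells (ENSMUSG00000039521.13; chromosome X, 7573644 to 7595245, GRCm38), stood at 633 ± 75.8 CPM in WT, 118 ± 22.8 CPM in Foxp3-deficient and 102 ± 13.7 CPM in double-deficient libraries. It fell 5.35-fold without working Foxp3 (log2 fold change −2.42, SE 0.14, edgeR adjusted p = 1.18e-08) and 6.198-fold in double-deficient against WT cells (log2 fold change −2.63, SE 0.14, edgeR adjusted p = 2.95e-09), both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13196 genes. Every deficient library lay below every WT library: the highest deficient value was 142 CPM and the lowest WT value 556 CPM. The difference between the deficient groups did not pass (log2 fold change −0.21, SE 0.13, edgeR adjusted p = 0.246), except without Foxp3-deficient 5 (−0.33, adjusted p = 0.0448). Rictor (ENSMUSG00000050310.9; chromosome 15, 6708379 to 6800401) stood at 148 ± 14.4 CPM in WT, 189 ± 31.2 CPM in Foxp3-deficient and 141 ± 12.6 CPM in double-deficient libraries. It was higher in Foxp3-deficient than in WT cells (log2 fold change 0.35, SE 0.11, edgeR adjusted p = 0.0494) and lower in double-deficient than in Foxp3-deficient cells (log2 fold change −0.42, SE 0.11, edgeR adjusted p = 0.0129), and between double-deficient and WT cells the difference did not pass (log2 fold change −0.08, SE 0.11, edgeR adjusted p = 0.626). The first of these calls was lost without WT 1, 3 or 5 or Foxp3-deficient 1 or 4 (log2 fold change 0.24 to 0.33), and with trends in length and GC content removed the second was lost (−0.11, adjusted p = 0.369) and the third turned to a rise (0.25, adjusted p = 0.0372). The counts cover whole genes and do not show which exons the reads came from, so the level of Rictor does not check the label of a conditional deletion.

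**Figure D2:**
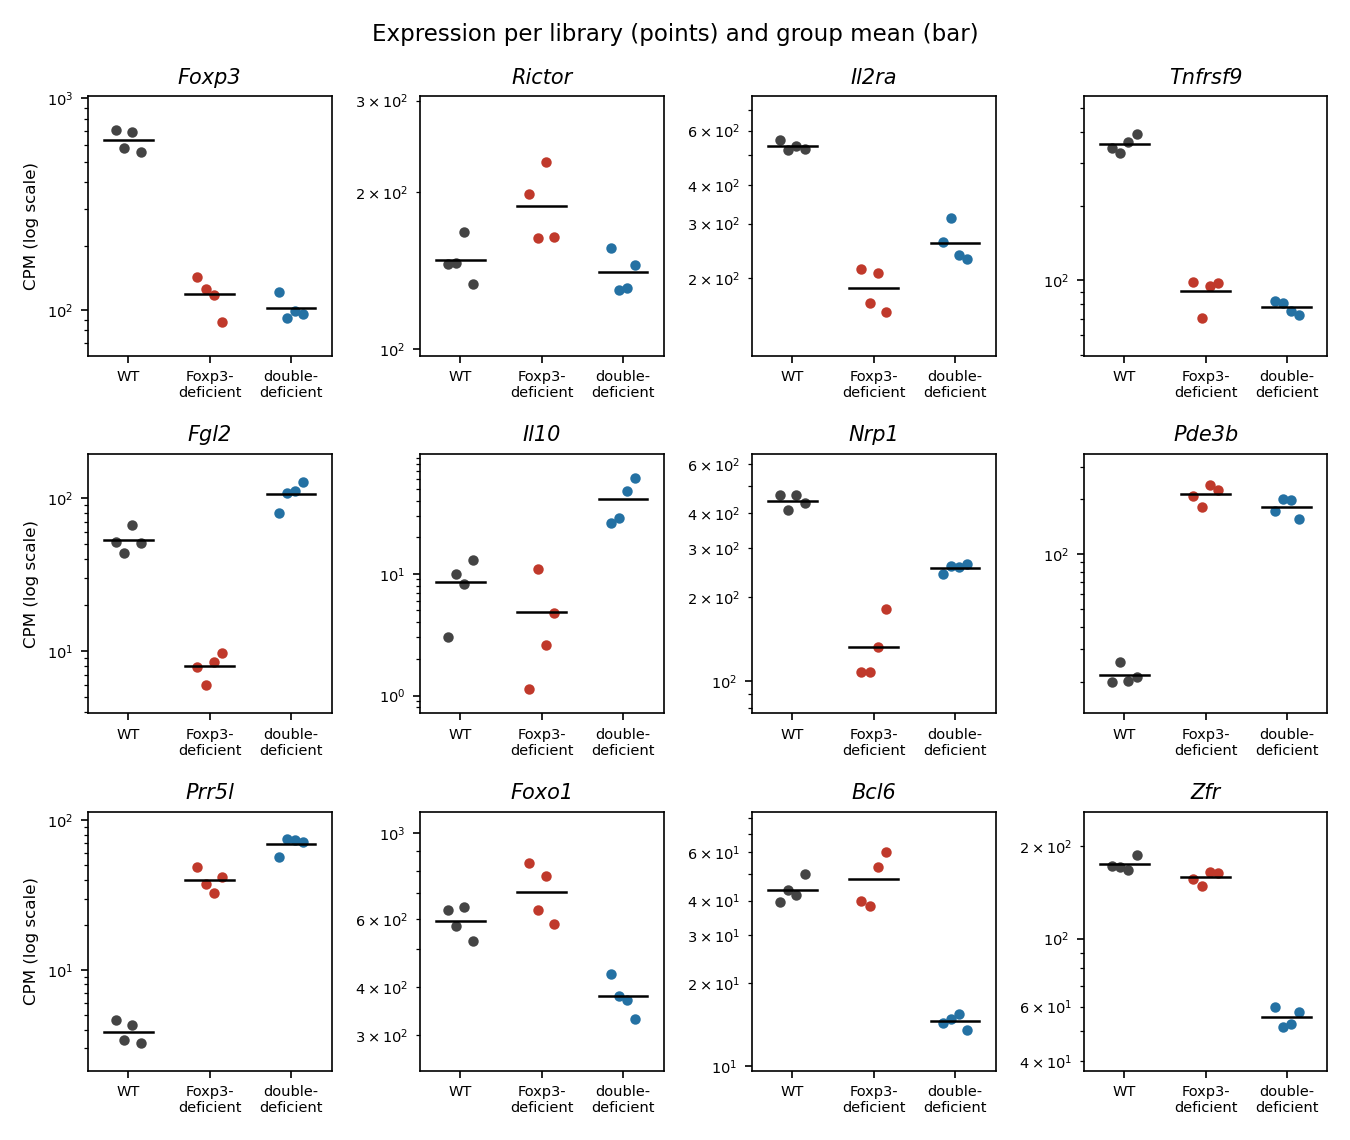
Expression (y axis, CPM, log scale) of 12 genes in each of the 12 libraries (points; x axis, WT, Foxp3-deficient and double-deficient groups), with a bar at each group mean. Foxp3 lay between 556 and 705 CPM in WT and between 87.9 and 142 CPM in both deficient groups, while Fgl2 stood at 53.3, 8.02 and 107 CPM.

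The comparison of Foxp3-deficient with WT cells asks what the cells lose and gain without working Foxp3. Much of the Treg signature fell: 25 of its 30 measured genes were lower and 1, Socs2, a feedback inhibitor of cytokine signalling, was higher. Tnfrsf9, the costimulatory receptor 4-1BB, fell 3.97-fold (90.1 ± 13.3 against 357 ± 27.2 CPM), and Fgl2, a secreted suppressive protein, fell 6.61-fold (8.02 ± 1.57 against 53.3 ± 9.64 CPM). Il2ra, the high-affinity chain of the interleukin-2 receptor, fell 2.88-fold (186 ± 29.4 against 534 ± 17.6 CPM) and Nrp1, a surface receptor common on thymus-derived Treg cells, fell 3.34-fold (133 ± 35 against 444 ± 27 CPM). Each of these 4 falls had an edgeR adjusted p of 3.22e-07 or less. Ctla4, an inhibitory receptor of Treg cells, stood at 246 ± 95.4 against 349 ± 23.3 CPM and did not pass (log2 fold change −0.51, SE 0.18, edgeR adjusted p = 0.0857), except without Foxp3-deficient 3 (−0.81, adjusted p = 1.18e-05). The whole list was lower (median log2 fold change −1.40, camera adjusted p = 1.61e-55, and adjusted p = 0.000419 with an estimated correlation). In it, 1 rose and 27 fell, adjusted over the list alone. Markers of B cells moved with it: 5 of 8 fell (Ighm, Fcmr, Cd79b, Igkc and Bank1; camera adjusted p = 2.59e-07, and adjusted p = 0.0395 with an estimated correlation), Ighm, the immunoglobulin heavy chain gene, by 1.87-fold (733 ± 69.7 against 1368 ± 96.7 CPM). Bank1 was no longer past the test without WT 1 or 4 or Foxp3-deficient 1 or 4 (log2 −0.98 to −0.81), and reads of immunoglobulin segments can be shared between genes.

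Genes of naive and resting T cells rose in 12 of 18 cases. Pde3b, a cyclic nucleotide phosphodiesterase, rose 9.84-fold, Igfbp4, a binding protein of insulin-like growth factors, rose 3.01-fold, and Tcf7, a transcription factor of resting and memory T cells, rose 2.15-fold from an already high level (2907 ± 198 against 1351 ± 50 CPM), with edgeR adjusted p values of 2.09e-06 or less. Ly6c1, a surface protein, was the 1 member that fell (log2 fold change −1.27, SE 0.26, edgeR adjusted p = 0.00441). The set test passed (camera adjusted p = 1.24e-16, and adjusted p = 0.00231 with an estimated correlation). Within it, 12 rose and 1 fell, adjusted over the list alone. In the Th17 program, 7 of 11 genes rose. Il1r1, the interleukin-1 receptor, rose 9.86-fold and Ahr, a ligand-activated transcription factor, rose 1.85-fold. Il17a itself gave 253 reads in Foxp3-deficient and 1 read in WT libraries, a ratio of 278 with a 95% counting interval of 49.5 to 11000, and Il17f gave 147 reads against 1 (ratio 162, 28.5 to 6420). Without Foxp3-deficient 3, 103 and 58 reads were left (ratios 143, 25.2 to 5720, and 80.8, 13.9 to 3250). WT had 0 reads of Il17a without WT 4 (at least 62.9-fold) and of Il17f without WT 1 (at least 42.7-fold). Batf and Irf4, transcription factors shared by several effector lineages, fell in the same list. Batf was no longer past the test without WT 1, 3, 4 or 5 or Foxp3-deficient 3 or 4 (log2 −0.76 to −0.64), nor Irf4 without WT 1, 3, 4 or 5 or Foxp3-deficient 4 (log2 −0.51 to −0.34). The list as a whole was higher (camera adjusted p = 2.48e-07, and adjusted p = 0.00231 with an estimated correlation). Here 7 rose and 2 fell, adjusted over the list alone.

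Of helper cytokine genes, 6 of 14 rose and 2 fell. Cd40lg, the ligand that T cells use to help B cells, rose 2.695-fold (edgeR adjusted p = 4.58e-07), whereas Lta, which encodes lymphotoxin, fell (log2 fold change −0.73, SE 0.12, edgeR adjusted p = 0.000482) and so did Tnfsf11, the ligand RANKL, whose call was lost without WT 3, 4 or 5 or Foxp3-deficient 1, 3 or 4 (log2 −0.53 to −0.41). The list passed with the preset correlation (camera adjusted p = 0.0155; adjusted p = 0.504 with an estimated correlation). In it, 6 rose and 3 fell, adjusted over the list alone. In the Th1 program, 6 of 16 rose and 0 fell, among them Il18r1, a receptor for interleukin-18, by 2.46-fold (camera adjusted p = 0.0184; adjusted p = 0.563 with an estimated correlation). Within it, 7 rose and 0 fell, adjusted over the list alone. Without Foxp3-deficient 5 both set calls were lost (camera adjusted p = 0.0547 for helper cytokines and 0.723 for the Th1 program), the second also without WT 3 (0.0698). Th2 genes went both ways: Ccr8, a chemokine receptor, fell 6.001-fold, Il1rl1, the interleukin-33 receptor, fell 4.24-fold and Gata3, the Th2 transcription factor, fell 1.36-fold, while Ccr4 rose (log2 fold change 0.58, SE 0.11) together with Maf and Plac8, whose calls were lost without WT 1, 3 or 5 or Foxp3-deficient 4 or 5 (log2 0.28 to 0.42) and without WT 1, 3, 4 or 5 (log2 1.63 to 1.93). Plac8 stood at 0.92 without Foxp3-deficient 3. That list had a median of 0.10 and a mean of −0.29 and did not pass (camera adjusted p = 0.345). Here 3 rose and 3 fell, adjusted over the list alone.

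Inhibitory receptor genes fell in 6 of 12 cases, for example Entpd1, the ectonucleotidase CD39, by 2.54-fold, Pdcd1lg2 by 3.398-fold and Tox, a regulator of chronically stimulated T cells, by 1.61-fold (camera adjusted p = 2.09e-05; adjusted p = 0.119 with an estimated correlation). In it, 1 rose and 9 fell, adjusted over the list alone. Among components of the mTOR and PI3K-AKT pathways, 7 of 31 rose and 1 fell. Prr5l, which encodes a protein that binds mTOR complex 2, rose 10.3-fold, and Sgk1, a kinase that this complex activates, rose 4.101-fold, while Phlpp1, a phosphatase that acts on AKT, fell 4.63-fold, each with an edgeR adjusted p of 5.29e-06 or less. Foxo1, a transcription factor that AKT inhibits, did not pass (log2 fold change 0.25, SE 0.12, edgeR adjusted p = 0.179). The set test gave camera adjusted p = 0.00644 (adjusted p = 0.22 with an estimated correlation). Within it, 10 rose and 1 fell, adjusted over the list alone. Proliferation genes rose in 13 of 30 cases and fell in 0, such as E2f1 (2.34-fold), Stmn1 (2.38-fold) and Rrm2 (1.99-fold; camera adjusted p = 1.53e-06; adjusted p = 0.316 with an estimated correlation). Here 20 rose and 0 fell, adjusted over the list alone. Homing and chemokine receptor genes rose in 11 of 25 cases, among them Ccr7, the lymph node homing receptor (1.64-fold), and fell in 3: Itgae, the integrin CD103 (9.23-fold), Ccr8, and Ccr3 (15.6-fold, or 30.97-fold without Foxp3-deficient 5). That list did not pass (camera adjusted p = 0.114), though it did without Foxp3-deficient 3 (0.0438) or 4 (0.0424). In it, 12 rose and 4 fell, adjusted over the list alone.

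Among called genes with a mean of at least 10 CPM over all 12 libraries and no overlap between the groups compared (unnamed gene models, pseudogenes and receptor segments left out), the largest rises were those of Pdlim4, a cytoskeletal adaptor (138-fold), Wnt5b, a secreted signalling protein (41.7-fold, or 111-fold without WT 4), Ccl20, a chemokine that attracts CCR6-bearing cells (41.3-fold, or 27.1-fold without Foxp3-deficient 3), and Ggt5, a gamma-glutamyl transferase (35.3-fold), followed by Emp1 (17.03-fold), Fam20a (11.9-fold) and Plekhf1 (11.2-fold). The largest falls among such genes were those of Sdc4, a heparan sulfate proteoglycan (10.5-fold), Axl, a receptor tyrosine kinase (9.93-fold), Itgae, Cd74, the invariant chain of antigen presentation (8.95-fold), Il1r2, a decoy receptor for interleukin-1 (7.87-fold), Epcam (7.83-fold) and Ttn (6.98-fold). All of these had an edgeR adjusted p of 8e-05 or less. Klrg1, a receptor of terminally differentiated cells, also fell (log2 fold change −2.95, SE 0.83, edgeR adjusted p = 0.0406), but not past the test without WT 1, 3, 4 or 5 or Foxp3-deficient 1, 3 or 4 (log2 −3.03 to −2.60), and stood at −4.98 without Foxp3-deficient 5. In all, 1812 of 13196 genes passed edgeR's test at the Benjamini-Hochberg threshold of 0.05 (923 higher and 889 lower in Foxp3-deficient cells), 781 of them with at least a 2-fold difference. With both Foxp3-deficient libraries that lay apart (replicates 1 and 3) left out, a setting chosen after seeing the data, 1751 genes passed.

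Of Tfh genes, Slamf6 (0.57), Il21 (3.10, or 2.24 without Foxp3-deficient 5) and Ppp1r14c rose and Icos (−0.73), Sh2d1a (−0.83) and Pdcd1, the receptor PD-1, fell out of 14. The values in brackets are log2 fold changes. Ppp1r14c had 142 reads in Foxp3-deficient and 0 in WT libraries, at least 52-fold with a floor of 3 reads over the group, and Pdcd1 was no longer past the test without WT 1, 3, 4 or 5 or Foxp3-deficient 1, 3 or 4 (log2 −1.12 to −0.80). The list median was −0.04 and the mean 0.78 (median −0.04 and mean 0.59 with Ppp1r14c at its bound; camera adjusted p = 0.979). Within it, 3 rose and 5 fell, adjusted over the list alone. Without both Foxp3-deficient 1 and 3 it turned upward (0.23, 0.0452). Of 13 cytotoxic and NK receptor genes, Klrk1 (49.9-fold, or 200 reads against 1, ratio 174, 30.9 to 6910, without WT 1), Gzmk, Klrd1 (88 reads against 3, ratio 32.2, 10.7 to 159) and Fasl rose and Gzmc fell (median −0.11, mean 0.86, camera adjusted p = 0.38). Here 5 rose and 3 fell, adjusted over the list alone. Fasl was not past the test without WT 4 or 5 or Foxp3-deficient 5 (log2 0.58 to 0.70). T cell receptor-induced genes fell in 4 of 16 cases, Tnfrsf9, Ikzf2, the Treg transcription factor Helios (2.47-fold), Egr2 (1.68-fold) and Irf4 (camera adjusted p = 0.0158; adjusted p = 0.22 with an estimated correlation; 0.0682 without Foxp3-deficient 1). In it, 2 rose and 6 fell, adjusted over the list alone. Irf4 was lost as in the Th17 list. Interferon response genes fell in 5 of 25 cases, among them Oas1a (2.66-fold), Gbp3 (1.74-fold), Gbp7 (1.54-fold) and Gbp2, while Ifit2 rose (camera adjusted p = 0.0188; adjusted p = 0.563 with an estimated correlation; 0.0851 without Foxp3-deficient 1). Within it, 1 rose and 9 fell, adjusted over the list alone. Of these, Gbp2 was lost without WT 5 or Foxp3-deficient 3 (log2 −0.35 to −0.32) and Ifit2 without WT 1, 3, 4 or 5 or Foxp3-deficient 1, 3 or 4 (log2 0.30 to 0.40). Apoptosis and survival genes fell in 5 of 20 cases, among them Bid (1.98-fold), Bbc3 (1.36-fold), Bcl2l1 and Fas, and Fasl rose (camera adjusted p = 0.0174; adjusted p = 0.241 with an estimated correlation; 0.0547 without Foxp3-deficient 1). Here 2 rose and 6 fell, adjusted over the list alone. Fas was lost without WT 3 or 5 or Foxp3-deficient 4 (log2 −0.48 to −0.40).

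Of 23 glycolysis genes, Slc2a3, a glucose transporter (2.77-fold), Slc16a3, a lactate transporter (2.36-fold), and Aldoc fell (median 0.06, mean −0.13, camera adjusted p = 0.264). In it, 2 rose and 6 fell, adjusted over the list alone. Of 22 genes of the TCA cycle, Idh2 (1.51-fold) and Ogdh rose (camera adjusted p = 0.416). Within it, 1 rose and 0 fell, adjusted over the list alone. Of 22 sterol and fatty acid synthesis genes Lss and Srebf2 rose (camera adjusted p = 0.18, 0.0359 without Foxp3-deficient 3). Here 2 rose and 0 fell, adjusted over the list alone. Aldoc was not past the test without WT 1, 4 or 5 or Foxp3-deficient 1, 3 or 4 (log2 −0.81 to −0.71), Ogdh without WT 1, 3, 4 or 5 or Foxp3-deficient 1, 4 or 5 (log2 0.22 to 0.27), Lss without WT 4 or 5 (log2 0.42 to 0.44) or Srebf2 without WT 3, 4 or 5 or Foxp3-deficient 1 or 4 (log2 0.20 to 0.29). Of 77 nuclear genes of oxidative phosphorylation (OXPHOS nuclear), Atp5s fell (camera adjusted p = 0.0341; adjusted p = 0.741 with an estimated correlation). The list call was lost without WT 1 (0.0698) or 5 (0.0867) or Foxp3-deficient 1 (0.948). In it, 0 rose and 0 fell, adjusted over the list alone. Of 7 mitochondrially encoded ones, mt-Nd6 fell (camera adjusted p = 0.0539). Within it, 0 rose and 2 fell, adjusted over the list alone. The set passed without WT 1 or 4 or Foxp3-deficient 3 or 4 (adjusted p = 0.0104 to 0.0424). Atp5s was lost without WT 1, 3, 4 or 5 or Foxp3-deficient 1 or 5 (log2 −0.70 to −0.52) and mt-Nd6 without WT 4 or 5 (log2 −0.46 to −0.35). Of 80 ribosomal protein genes 0 passed in edgeR (5 had an unadjusted p under 0.05, and 3 passed in DESeq2 and 0 in limma-voom), Rpl4 for example standing at 1035 ± 194 against 945 ± 72.8 CPM (camera adjusted p = 0.31; 0.0473 without WT 4 and 0.00577 without Foxp3-deficient 3). Here 0 did, adjusted over the list alone. Rpl4 passed without Foxp3-deficient 1 (log2 fold change 0.25). Of 18 dissociation and heat shock genes 0 passed in edgeR (6 unadjusted; 3 in DESeq2 and 1 in limma-voom), with Junb at 7474 ± 5400 against 3560 ± 1220 CPM (camera adjusted p = 0.0527). Here 0 did, adjusted over the list alone. The set passed without WT 3 or 5 or Foxp3-deficient 1 or 4 (adjusted p = 0.00269 to 0.0424).

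Plasma cell markers fell in 2 of 4 cases: Ighg3, with 3 reads in Foxp3-deficient and 252 in WT libraries (ratio 76.4, 25.9 to 373, or at least 53.6-fold without Foxp3-deficient 5), and Xbp1, which was lost without WT 3, 4 or 5 or Foxp3-deficient 4 (log2 −0.27 to −0.22) (camera adjusted p = 0.0362; adjusted p = 0.152 with an estimated correlation). Here 0 rose and 2 fell, adjusted over the list alone. The set was lost without WT 1 (0.0793) or 5 (0.0504) or Foxp3-deficient 1 (0.0682) or 5 (0.0686). Dendritic cell markers held 1 rise, Ccr9, a gut homing receptor (2.72-fold), and 2 falls, Cd74 and Irf8 (1.82-fold), among 8 genes (camera adjusted p = 0.0155; adjusted p = 0.152 with an estimated correlation). In it, 1 rose and 3 fell, adjusted over the list alone. Fcgr3 rose among 3 myeloid markers, but not without WT 1, 3 or 5 or Foxp3-deficient 3 or 5 (log2 1.35 to 1.72), and by 3.28-fold in all or 6.47-fold without WT 4 (camera adjusted p = 0.287). Within the list, 2 rose and 0 fell, adjusted over the list alone. Itgb3, an integrin chain, rose 1.99-fold among 2 platelet markers (camera adjusted p = 0.0341; adjusted p = 0.152 with an estimated correlation; 0.0619 without Foxp3-deficient 1). Here 1 rose and 0 fell, adjusted over the list alone. Of 5 NK and CD8 cell markers 0 passed in edgeR (3 unadjusted; 1 in DESeq2 and 0 in limma-voom), Cd8b1 standing at 16.9 ± 2.56 against 18.2 ± 1.91 CPM (camera adjusted p = 0.799). In it, 2 rose and 1 fell, adjusted over the list alone. 0 of 10 erythroid markers had enough reads to be tested in any comparison.

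**Figure D3:**
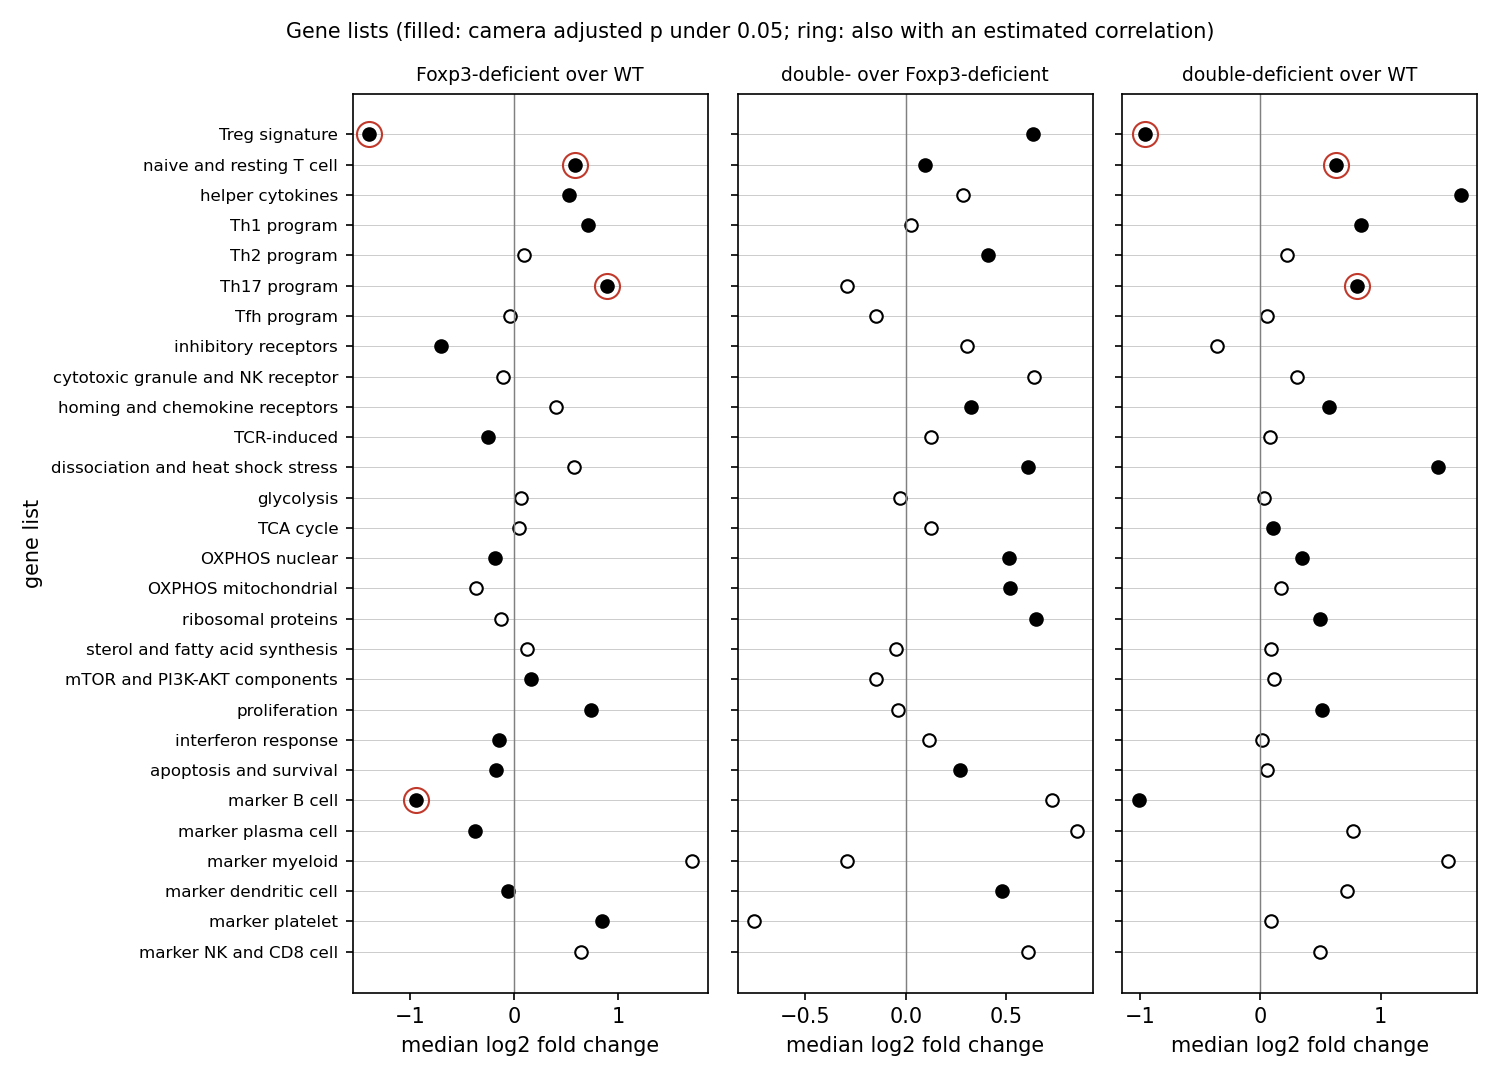
Median log2 fold change (x axis) of 28 gene lists (y axis) in the 3 comparisons (3 panels). Filled points passed the camera test with a preset correlation and ringed ones also with an estimated correlation. The Treg signature stood at −1.40, 0.63 and −0.96, ringed in the first and the third panel.

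The comparison of double-deficient with Foxp3-deficient cells asks what changes when Rictor is lost on top of Foxp3. Part of the Treg signature rose: 17 of its 30 measured genes were higher and 0 lower. Fgl2 rose 13.2-fold (107 ± 20 against 8.02 ± 1.57 CPM), Gpr83, an orphan receptor of Treg cells, rose 2.29-fold, Capg, an actin-capping protein, rose 1.89-fold and Il10, an anti-inflammatory cytokine, rose 8.48-fold (40.9 ± 16.5 against 4.88 ± 4.34 CPM, or 14.1-fold without Foxp3-deficient 3), with edgeR adjusted p values of 0.00575 or less. Nrp1 rose 1.92-fold and Il2ra rose 1.404-fold, whereas 3 other members gave no call: Tnfrsf9 (log2 fold change −0.22, SE 0.10, edgeR adjusted p = 0.124), Ikzf2 (log2 fold change −0.40, SE 0.18, edgeR adjusted p = 0.113) and Ctla4 (log2 fold change 0.50, SE 0.18, edgeR adjusted p = 0.0564). Without Foxp3-deficient 3 these 3 passed (−0.32, −0.54 and 0.81 in that order). The list was higher with the preset correlation (camera adjusted p = 5.95e-12; adjusted p = 0.0981 with an estimated correlation). Within it, 19 rose and 0 fell, adjusted over the list alone.

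Th2 genes rose in 5 of 9 cases and fell in 0. Plac8, a small cysteine-rich protein, rose 16.2-fold (29.3-fold without Foxp3-deficient 3), Il4, the signature Th2 cytokine, rose 7.15-fold (9.44 ± 3.99 against 1.299 ± 0.715 CPM), Il1rl1 rose 3.41-fold, and Il10 and Gata3 completed the set, Gata3 being lost without Foxp3-deficient 4 or double-deficient 5 (log2 0.22 to 0.23). The set test gave camera adjusted p = 0.00375 (adjusted p = 0.163 with an estimated correlation). Here 5 rose and 1 fell, adjusted over the list alone. Helper cytokine genes rose in 4 of 14 cases, Il4, Il10, Ltb (1.85-fold) and Tnfsf8 (1.44-fold), and Cd40lg fell, though not without Foxp3-deficient 4 or 5 or double-deficient 3, 4 or 5 (log2 −0.37 to −0.24). The list did not pass (camera adjusted p = 0.0521) except without Foxp3-deficient 3 or 5 or double-deficient 2, 3 or 4 (adjusted p = 0.0131 to 0.0486). In it, 4 rose and 2 fell, adjusted over the list alone. Homing receptor genes rose in 10 of 25 cases, for example Gpr15 (3.08-fold) and Ccr9 (2.698-fold), and fell in 2, Cxcr5, the follicle homing receptor (2.73-fold), and Itga4, which was lost without Foxp3-deficient 1 or 4 or double-deficient 3, 4 or 5 (log2 −0.39 to −0.30) (camera adjusted p = 0.00419; adjusted p = 0.535 with an estimated correlation). Within it, 11 rose and 3 fell, adjusted over the list alone. Without both Foxp3-deficient 1 and 3 that set no longer passed (0.146). Of 18 naive and resting T cell genes 5 rose, among them Igfbp4 (2.38-fold), Dapl1 (3.88-fold), Il7r, the interleukin-7 receptor (1.62-fold), and Ly6c1, and 2 fell, Satb1 (−0.51) and Foxp1 (−0.36). Pde3b did not pass (log2 fold change −0.23, SE 0.11, edgeR adjusted p = 0.122; −0.30 and adjusted p = 0.0423 without Foxp3-deficient 3). Ly6c1 was lost without double-deficient 5 (log2 0.80) and Foxp1 without double-deficient 5 (log2 −0.31), and with trends in length and GC content removed Satb1 (−0.10) and Foxp1 (−0.04) were lost. The set test gave camera adjusted p = 0.0348 (adjusted p = 0.535 with an estimated correlation; 0.114 without Foxp3-deficient 5 and 0.0575 without double-deficient 2). Here 5 rose and 2 fell, adjusted over the list alone.

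Among mTOR and PI3K-AKT components 4 of 31 rose and 10 fell. Foxo1 fell 1.87-fold (378 ± 42 against 706 ± 118 CPM, edgeR adjusted p = 0.000152), while Foxo3, a second transcription factor of that family (2.79-fold), Prr5l (1.72-fold), Pik3r5 and Eif4ebp1 rose. Sgk1 did not pass (log2 fold change −0.06, SE 0.19, edgeR adjusted p = 0.834). Eif4ebp1 was lost without Foxp3-deficient 4 or double-deficient 5 (log2 0.70 to 0.71). The list did not pass (camera adjusted p = 0.16). In it, 6 rose and 12 fell, adjusted over the list alone. Genes of the inhibitory receptor list rose in 3 of 12 cases, Lag3 (2.74-fold), Havcr2, the receptor TIM-3 (6.31-fold, or 12.3-fold without Foxp3-deficient 3), and Cd200 (1.31-fold). The list gave camera adjusted p = 0.0521, and 0.0179 to 0.0451 without Foxp3-deficient 4 or 5 or double-deficient 4. Within it, 4 rose and 0 fell, adjusted over the list alone. Apoptosis and survival genes rose in 8 of 20 cases, such as Bid (1.88-fold) and Bbc3 (1.52-fold), both promoters of cell death, and Cflar, an inhibitor of death receptors, fell (camera adjusted p = 0.00437; adjusted p = 0.453 with an estimated correlation). Here 9 rose and 1 fell, adjusted over the list alone. Tfh genes split: Slamf6 (1.86-fold), Sh2d1a (1.79-fold), Icos (1.49-fold) and Cd200 rose, and Bcl6, the Tfh transcription factor (3.29-fold), and Cxcr5 fell, out of 14 (median −0.15, mean −0.36, test upward, camera adjusted p = 0.761). In it, 4 rose and 2 fell, adjusted over the list alone. Without both Foxp3-deficient 1 and 3 the test turned downward (−0.58, 0.0254).

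The energy and protein synthesis lists rose in many small steps. Of 77 OXPHOS nuclear genes 44 rose and 0 fell, for example Ndufs4 of complex I (1.87-fold), Uqcrc2 of complex III (1.43-fold) and Atp5j of the ATP synthase (1.68-fold), and of 80 ribosomal protein genes 49 rose and 0 fell, for example Rpl7 (2.14-fold), Rps18 (2.08-fold) and Rps19 (1.96-fold). The medians were 0.51 (camera adjusted p = 1.03e-12; adjusted p = 0.535 with an estimated correlation) and 0.65 (camera adjusted p = 5.46e-11; adjusted p = 0.535 with an estimated correlation). In the first list 53 rose and 0 fell, adjusted over the list alone. In the second, 52 rose and 0 fell, adjusted over the list alone. These are short transcripts, and the trend with length, the lower share of reads outside genes and the higher share of reads without a unique alignment moved with them. Reads of ribosomal protein genes can also be shared with pseudogenes. With trends in length and GC content removed, 28 and 34 genes still rose and 1 fell in each list, with medians above that of all genes of 0.22 in place of 0.54 and of 0.38 in place of 0.68. Of 7 mitochondrially encoded genes mt-Nd1 rose (camera adjusted p = 0.0342; adjusted p = 0.535 with an estimated correlation; 0.0828 without Foxp3-deficient 1). Here 5 rose and 0 fell, adjusted over the list alone. This call was lost without Foxp3-deficient 4 or double-deficient 5 (log2 0.62 to 0.74), and with length and GC trends removed gene and list turned downward (−0.08 and −0.20). Of 22 TCA cycle genes Sucla2 (1.45-fold), Dld (1.42-fold), Sdhd (1.48-fold) and Mdh1 (1.62-fold) rose and Ogdh fell, though not without double-deficient 5 (log2 −0.27) (camera adjusted p = 0.0521, and 0.0247 to 0.0458 without Foxp3-deficient 4 or 5 or double-deficient 4 or 5). In it, 4 rose and 1 fell, adjusted over the list alone.

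Within the same limits of level and overlap, the largest rises were those of Plac8, Fgl2, Il10, Cysltr1, a leukotriene receptor (7.26-fold), Pcsk1, a prohormone convertase (6.85-fold), and Lgals3, a galectin (6.15-fold, or 9.63-fold without Foxp3-deficient 5). Eno1b (34.6 ± 23.7 against 0.127 ± 0.046 CPM) and Gbp2b (7.704-fold) also rose, but near-identical copies (Eno1 and Gbp2) can share their reads, so their levels are uncertain. Within these limits the largest falls were those of Rab6b, a vesicle transport GTPase (10.9-fold, or 18.5-fold without double-deficient 4), Mmp14, a membrane metalloproteinase (7.54-fold), Ptprv (4.56-fold), Bcl6, Slc16a5 (3.24-fold), Zfr, an RNA-binding zinc finger protein (2.86-fold, edgeR adjusted p = 8.69e-09), Cxcr5 and Wdfy1 (2.67-fold). Zfr lies on chromosome 15 between 12117831 and 12185683, within 15 Mb of Rictor. In all, 3585 of 13196 genes passed (1834 higher, 51.2%, and 1751 lower), 636 with at least a 2-fold difference. Without double-deficient 5 the number was 2153, and with trends in length and GC content removed, a setting chosen after seeing the data, it was 2747, of which 1894 (52.8% of the 3585) were the same genes. With the replicate number as a block besides, 63.2% of 1987 calls were higher. With Foxp3-deficient 1 and 3 left out, 2970 genes passed.

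In the Th1 program Stat4 (1.56-fold), Ccl4 (16.97-fold, or 39.6-fold without Foxp3-deficient 5) and Cxcr6 (2.49-fold) rose and Eomes and Il12rb2 fell, out of 16 (camera adjusted p = 0.178, and 9.26e-06 without Foxp3-deficient 5). Within it, 3 rose and 2 fell, adjusted over the list alone. Eomes was lost without Foxp3-deficient 1, 4 or 5 or double-deficient 3, 4 or 5 (log2 −0.79 to −0.53) and Il12rb2 without Foxp3-deficient 5 or double-deficient 2, 3, 4 or 5 (log2 −2.43 to −0.40). In the Th17 program Irf4 (1.47-fold) and Batf rose and 3 of 11 genes fell, among them Il1r1 and Stat3 (camera adjusted p = 0.533). Here 2 rose and 5 fell, adjusted over the list alone. Batf was lost without Foxp3-deficient 4 or double-deficient 3, 4 or 5 (log2 0.62 to 0.69), Il1r1 without Foxp3-deficient 1 or double-deficient 3 or 4 (log2 −1.05 to −0.97) and Stat3 without Foxp3-deficient 1 or double-deficient 5 (log2 −0.29 to −0.26). With length and GC trends removed Stat3 turned upward (0.03). Cytotoxic genes held 1 rise, Srgn, and 1 fall, Ctsw, out of 13 (camera adjusted p = 0.163, and 0.0144 without Foxp3-deficient 5). Here 1 rose and 1 fell, adjusted over the list alone. Srgn was lost without Foxp3-deficient 4 or double-deficient 3, 4 or 5 (log2 0.80 to 0.88) and Ctsw without double-deficient 3 (log2 −0.29). T cell receptor-induced genes held 3 rises out of 16, Irf4, Dusp2 and Nfkbia (camera adjusted p = 0.444, and 0.038 without Foxp3-deficient 3). Within it, 3 rose and 0 fell, adjusted over the list alone. Dusp2 was lost without Foxp3-deficient 1, 4 or 5 or double-deficient 2, 4 or 5 (log2 0.42 to 0.51) and Nfkbia without Foxp3-deficient 4 or 5 or double-deficient 3, 4 or 5 (log2 0.72 to 0.85). Stress genes held 3 rises out of 18, Ier3 (7.76-fold), Zfp36 (1.796-fold) and Ier2, lost without Foxp3-deficient 1, 4 or 5 or double-deficient 2, 3, 4 or 5 (log2 0.65 to 0.88) (camera adjusted p = 0.00375; adjusted p = 0.535 with an estimated correlation). Here 3 rose and 0 fell, adjusted over the list alone. Interferon response genes held 5 rises, Gbp3 (2.38-fold), Ifi27l2a (2.24-fold), Bst2, Gbp2 and Isg20, and 1 fall, Stat2 (1.404-fold), out of 25 (camera adjusted p = 0.0655, and 0.0114 to 0.0451 without Foxp3-deficient 3 or 4 or double-deficient 4 or 5). In it, 7 rose and 1 fell, adjusted over the list alone. Bst2 was lost without Foxp3-deficient 1 or 4 or double-deficient 2, 3, 4 or 5 (log2 0.31 to 0.52), Gbp2 without Foxp3-deficient 4 or double-deficient 3 (log2 0.32 to 0.37) and Isg20 without Foxp3-deficient 4 or double-deficient 3 or 5 (log2 0.49 to 0.61).

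Glycolysis genes split evenly: Ldhb (1.64-fold), Tpi1 (1.54-fold), Ldha and Pkm rose and Pfkfb3 (1.32-fold), Hk1, Pfkm and Pfkp fell, out of 23 (median −0.03, mean 0.04, camera adjusted p = 0.795). Within it, 4 rose and 4 fell, adjusted over the list alone. Ldha was lost without Foxp3-deficient 1 or double-deficient 3 or 5 (log2 0.23 to 0.30), Pkm without Foxp3-deficient 1, 3 or 4 or double-deficient 3, 4 or 5 (log2 0.20 to 0.26), Hk1 without Foxp3-deficient 1, 4 or 5 or double-deficient 2, 4 or 5 (log2 −0.30 to −0.23), Pfkm without Foxp3-deficient 1 or 4 or double-deficient 2, 4 or 5 (log2 −0.59 to −0.38) and Pfkp without Foxp3-deficient 1, 4 or 5 or double-deficient 2, 3, 4 or 5 (log2 −0.28 to −0.20), and with length and GC trends removed Hk1 (0.08) and Pfkp (0.11) turned upward. Of 22 sterol genes Cyp51 and Msmo1 rose (median −0.05, test upward, camera adjusted p = 0.934). Here 0 rose and 0 fell, adjusted over the list alone. Cyp51 was lost without Foxp3-deficient 3, 4 or 5 or double-deficient 3 or 5 (log2 0.31 to 0.32) and Msmo1 without Foxp3-deficient 3, 4 or 5 or double-deficient 2, 3, 4 or 5 (log2 0.23 to 0.31). Of 30 proliferation genes Hmgb2 rose (1.64-fold) and Mcm4 fell (1.26-fold; median −0.04, test upward, camera adjusted p = 0.964). In it, 1 rose and 1 fell, adjusted over the list alone. Among B cell markers Cd79b (1.87-fold) and Igkc rose and Cd22 fell (4.599-fold, or 8.02-fold without double-deficient 3), out of 8 (camera adjusted p = 0.132, and 0.047 without Foxp3-deficient 3). Within it, 5 rose and 1 fell, adjusted over the list alone. Igkc was lost without Foxp3-deficient 1, 4 or 5 or double-deficient 2, 3, 4 or 5 (log2 1.18 to 1.42). Among 4 plasma cell markers Jchain (13.2-fold, or 20.5-fold without Foxp3-deficient 3) and Sdc1 rose (camera adjusted p = 0.0859). Here 2 rose and 0 fell, adjusted over the list alone. Sdc1 was lost without Foxp3-deficient 5 or double-deficient 3 or 5 (log2 0.93 to 1.10). Among 8 dendritic cell markers Ccr9 rose (camera adjusted p = 0.0418; adjusted p = 0.453 with an estimated correlation; 0.0836 without Foxp3-deficient 1 and 0.0509 without 5). In it, 1 rose and 0 fell, adjusted over the list alone. Cd74 did not pass (log2 fold change 0.38, SE 0.16, edgeR adjusted p = 0.0835; 0.47 and adjusted p = 0.0394 without Foxp3-deficient 3). Among 3 myeloid markers Fcgr3 rose (median −0.29, mean 0.23, camera adjusted p = 0.795), but not without Foxp3-deficient 1 or 4 or double-deficient 2 or 5 (log2 1.38 to 1.56). Within the list, 1 rose and 0 fell, adjusted over the list alone. Of 2 platelet markers 0 passed in edgeR (1 unadjusted; 0 in DESeq2 and limma-voom), Itgb3 standing at 159 ± 21.3 against 159 ± 32.6 CPM (camera adjusted p = 0.686). Here 0 did, adjusted over the list alone. Of 5 NK and CD8 cell markers Cd8b1 rose (1.52-fold) and Eomes fell (camera adjusted p = 0.43). Here 1 rose and 1 fell, adjusted over the list alone.

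The comparison of double-deficient with WT cells gives their distance from intact Treg cells. The Treg signature stayed lower: 19 of 30 genes fell, Tnfrsf9 by 4.604-fold, Ikzf2 by 3.26-fold, Il2ra by 2.05-fold and Nrp1 by 1.74-fold. Another 3 members were higher than in WT cells: Fgl2 by 1.998-fold, Il10 by 4.76-fold and Socs2 by 3.27-fold. Ctla4 stood at 347 ± 21 against 349 ± 23.3 CPM and did not pass (log2 fold change −0.01, SE 0.18, edgeR adjusted p = 0.976). The set test passed (camera adjusted p = 7.32e-11, and adjusted p = 0.0423 with an estimated correlation). In it, 4 rose and 19 fell, adjusted over the list alone. Naive and resting T cell genes rose in 12 of 18 cases, such as Pde3b (8.37-fold), Igfbp4 (7.15-fold) and Il7r (2.93-fold; camera adjusted p = 3.8e-17, and adjusted p = 0.0059 with an estimated correlation). Within it, 12 rose and 0 fell, adjusted over the list alone. Th17 genes rose in 7 of 11 cases, among them Il23r, the interleukin-23 receptor (5.71-fold), and Il17a (454 reads against 1, ratio 470, 83.9 to 18600, or at least 106-fold without WT 4), and Stat3 fell (1.34-fold), a call lost with length and GC trends removed (−0.11). That set passed (camera adjusted p = 0.000213, and adjusted p = 0.0334 with an estimated correlation). Here 7 rose and 1 fell, adjusted over the list alone. With an estimated correlation, camera calls held against WT for the Treg signature, naive and resting T cell and Th17 lists in both deficient groups. Those of B cell markers held in Foxp3-deficient cells only. In double-deficient against Foxp3-deficient cells 0 held. There fry ran from adjusted p = 0.000215 (Treg signature) to 0.963 (proliferation).

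Helper cytokine genes rose in 10 of 14 cases, for example Tnfsf8 (2.14-fold) and Cd40lg (2.09-fold), and fell in 2, Lta (1.76-fold) and Tnfsf11, lost without WT 5 or double-deficient 2 (log2 −0.45 to −0.43) (camera adjusted p = 0.000105; adjusted p = 0.434 with an estimated correlation). In it, 10 rose and 2 fell, adjusted over the list alone. Th1 genes rose in 8 of 16 cases, among them Cxcr6, a tissue homing receptor (6.23-fold), Il18r1 (2.29-fold) and Stat4 (1.42-fold), and Il12rb1 fell (1.503-fold; camera adjusted p = 0.00164; adjusted p = 0.516 with an estimated correlation). Within it, 9 rose and 1 fell, adjusted over the list alone. Th2 genes rose in 4 of 9 cases, Plac8 (55.4-fold), Il4 (10.01-fold), Il10 and Ccr4, lost without WT 3 or 4 or double-deficient 3 (log2 0.27 to 0.31), and Ccr8 fell (4.52-fold; camera adjusted p = 0.14). Here 4 rose and 2 fell, adjusted over the list alone. Homing receptor genes rose in 16 of 25 cases, such as Ccr9 (7.35-fold), and fell in 3, Itgae (4.36-fold), Ccr8 and Cxcr5 (5.15-fold; camera adjusted p = 2e-04; adjusted p = 0.434 with an estimated correlation). In it, 16 rose and 3 fell, adjusted over the list alone. Among mTOR and PI3K-AKT components 7 of 31 rose, such as Prr5l (17.8-fold), Sgk1 (3.94-fold) and Pik3r5 (1.88-fold), and 8 fell, such as Phlpp1 (5.71-fold) and Foxo1 (1.57-fold; camera adjusted p = 0.376). Within it, 12 rose and 11 fell, adjusted over the list alone. Proliferation genes rose in 15 of 30 cases, such as Stmn1 (3.09-fold), E2f1 (2.39-fold) and Hmgb2 (2.07-fold), and fell in 0 (camera adjusted p = 0.000105; adjusted p = 0.516 with an estimated correlation). Here 19 rose and 0 fell, adjusted over the list alone. Stress genes, which also rise during cell isolation, rose in 12 of 18 cases and fell in 0, among them Zfp36 (2.54-fold), Ier2 (3.12-fold) and Ier3 (7.48-fold; camera adjusted p = 5.26e-05; adjusted p = 0.516 with an estimated correlation). In it, 14 rose and 0 fell, adjusted over the list alone.

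OXPHOS nuclear genes rose in 24 of 77 cases, such as Uqcrc2 (1.497-fold), Uqcrfs1 (1.68-fold) and Atp5b (1.29-fold), and fell in 0 (camera adjusted p = 6.99e-05; adjusted p = 0.627 with an estimated correlation). Within it, 19 rose and 0 fell, adjusted over the list alone. Ribosomal protein genes rose in 36 of 80 cases, such as Rpl4 (1.54-fold) and Rps4l, whose reads can be shared with a near-identical copy, and fell in 0 (camera adjusted p = 1.56e-05; adjusted p = 0.557 with an estimated correlation). Here 39 rose and 1 fell, adjusted over the list alone. The shares of reads outside genes and of reads without a unique alignment differed here too, as did the trend with length (Spearman rho across genes −0.353). TCA cycle genes rose in 6 of 22 cases, such as Idh2 (1.5-fold), Sucla2 (1.52-fold) and Dld (1.47-fold; camera adjusted p = 0.0238; adjusted p = 0.516 with an estimated correlation). In it, 6 rose and 0 fell, adjusted over the list alone. Of 7 mitochondrially encoded genes 0 passed in edgeR, 0 unadjusted and 0 in DESeq2 and limma-voom, with mt-Cytb at 1530 ± 207 against 1355 ± 399 CPM (camera adjusted p = 0.731). Here 0 did, adjusted over the list alone. With length and GC trends removed the list turned downward (−0.35, adjusted p = 0.00405). Of 22 sterol genes Fdft1 (1.35-fold), Cyp51 (1.38-fold), Mvd (1.38-fold) and Sqle (1.48-fold) rose and Scd2 fell, lost without double-deficient 2 or 5 (log2 −0.75 to −0.71) (camera adjusted p = 0.282). Within it, 4 rose and 1 fell, adjusted over the list alone. Of 23 glycolysis genes Ldha (1.43-fold), Pkm (1.25-fold), Ldhb and Tpi1 rose and Slc2a3 (2.45-fold), Slc16a3 (2.87-fold), Slc2a1 (1.27-fold) and Eno3 (1.55-fold) fell (median 0.03, mean −0.09, camera adjusted p = 0.569). Here 4 rose and 4 fell, adjusted over the list alone. Ldhb was lost without WT 3 or 4 or double-deficient 4 or 5 (log2 0.30 to 0.37) and Tpi1 without WT 1, 3 or 4 or double-deficient 3, 4 or 5 (log2 0.36 to 0.40).

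Inhibitory receptor genes fell in 6 of 12 cases, such as Entpd1 (2.08-fold) and Tox (1.64-fold), and Lag3 rose (2.46-fold; camera adjusted p = 0.126). In it, 1 rose and 6 fell, adjusted over the list alone. Of 14 Tfh genes Slamf6 (2.76-fold), Il21 (7.64-fold) and Ppp1r14c (75 reads against 0, at least 25.9-fold) rose and Bcl6 (3.01-fold), Cxcr5, Pdcd1 (2.21-fold) and Tox2 fell (median 0.05, mean 0.41, or 0.24 with Ppp1r14c at its bound, which leaves the median at 0.05; camera adjusted p = 0.731). Within it, 3 rose and 4 fell, adjusted over the list alone. Tox2 was lost without WT 3, 4 or 5 or double-deficient 2, 3, 4 or 5 (log2 −1.17 to −0.98). Of 13 cytotoxic and NK receptor genes Klrk1 (98.6-fold, or 435 reads against 1, ratio 356, 63.6 to 14100, without WT 1), Gzmk (22.8-fold), Klrd1 (150 reads against 3, ratio 51.7, 17.4 to 254), Gzma (9.64-fold) and Fasl (1.69-fold) rose and Ctsw fell (1.37-fold; camera adjusted p = 0.123). Here 5 rose and 3 fell, adjusted over the list alone. Of 16 T cell receptor-induced genes Dusp2 (1.89-fold), Nfkbia and Egr1 rose and Tnfrsf9, Ikzf2, Egr2 (1.63-fold), Nr4a2 (1.81-fold) and Nr4a3 fell (median 0.08, mean −0.08, camera adjusted p = 0.274). In it, 5 rose and 5 fell, adjusted over the list alone. Nfkbia was lost without WT 1 or double-deficient 5 (log2 0.80 to 0.82), Egr1 without WT 1, 3, 4 or 5 or double-deficient 2, 4 or 5 (log2 0.64 to 0.72) and Nr4a3 without WT 3 or 5 or double-deficient 3, 4 or 5 (log2 −0.78 to −0.54). Of 25 interferon response genes Gbp3 (1.36-fold), Ifi27l2a (1.803-fold), Ifit1 (1.45-fold) and Ifit3 rose and 5 fell, among them Oas1a (2.74-fold), Gbp7 (1.31-fold), Stat2 (1.29-fold) and Gbp4 (1.23-fold) (median and mean 0.02, test downward, camera adjusted p = 0.768). Within it, 4 rose and 5 fell, adjusted over the list alone. Ifit3 was lost without WT 3 or 5 or double-deficient 3 or 4 (log2 0.62 to 0.77). Of 20 apoptosis and survival genes Mcl1 (1.29-fold) and Fasl rose and Bcl2l1 (1.44-fold) and Cflar (1.42-fold) fell (camera adjusted p = 0.731). Here 2 rose and 2 fell, adjusted over the list alone. B cell markers fell in 6 of 8 cases, such as Ighm (1.61-fold), Fcmr (11.3-fold) and Bank1 (2.66-fold; camera adjusted p = 0.00467; adjusted p = 0.434 with an estimated correlation). In it, 0 rose and 6 fell, adjusted over the list alone. Of 4 plasma cell markers Jchain (9.395-fold, or 17.7-fold without WT 1) and Sdc1 (3.33-fold) rose and Ighg3 fell (median 0.77, mean −0.18, camera adjusted p = 0.785). Within it, 2 rose and 2 fell, adjusted over the list alone. Of 8 dendritic cell markers Ccr9 rose and Cd74 (6.88-fold) and Irf8 (1.63-fold) fell (median 0.72, mean 0.33, test downward, camera adjusted p = 0.731). Here 1 rose and 2 fell, adjusted over the list alone. Of 3 myeloid markers Fcgr3 rose (9.52-fold, or 18.8-fold without WT 4) and Cd68 fell, lost without WT 3 or 5 (log2 −0.99 to −0.98) (camera adjusted p = 0.337). In it, 2 rose and 1 fell, adjusted over the list alone. Itgb3 rose 2-fold among 2 platelet markers (camera adjusted p = 0.274). Within it, 1 rose and 0 fell, adjusted over the list alone. Cd8b1 (1.41-fold) and Gzma rose among 5 NK and CD8 cell markers (camera adjusted p = 0.391). Here 3 rose and 1 fell, adjusted over the list alone.

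Within the same limits, the largest rises against WT were those of Wnt5b (155-fold, or 413-fold without WT 4), Pdlim4 (131-fold), Ccl20 (72.9-fold), Plac8 (55.4-fold), Emp1 (41.2-fold), Pcsk1 (40.2-fold) and Ggt5 (22.03-fold), besides Eno1b with its shared reads. Wnt5b (3.72-fold) and Emp1 (2.42-fold) also rose from Foxp3-deficient to double-deficient cells. The largest falls within them were those of Rab6b (18.8-fold, or 32.1-fold without double-deficient 4), Abcb1a, a drug efflux pump (7.47-fold), Axl (7.32-fold), Cd74, Ttn (6.82-fold), Itgb8, an integrin that activates transforming growth factor beta (6.59-fold), and Susd2 (6.25-fold). These had edgeR adjusted p values of 0.00318 or less. Klrg1 fell as well (log2 fold change −3.00, SE 0.83, edgeR adjusted p = 0.0206), a call lost without double-deficient 2, 3 or 4 (log2 −2.90 to −2.82). In all, 4299 of 13196 genes passed (2084 higher and 2215 lower), 1237 with at least a 2-fold difference.

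The design also asks whether genes that changed without Foxp3 moved back when Rictor was lost too. Among genes called in both steps, 491 moved in opposite directions (236 up then down, 255 down then up) and 154 in the same direction (119 up and 35 down in both). Fgl2, Nrp1, Il2ra and Itgae (9.23-fold down, then 2.12-fold up, to 13.03 ± 2.59 CPM) fell and then rose, while Emp1, Wnt5b and Prr5l rose at both steps. Both steps share the Foxp3-deficient libraries, which by itself makes fold changes run against each other. In 20 simulations of unchanged groups at most 1 gene was opposite and 0 the same, no baseline as unchanged genes are rarely called. Independent lists of these sizes would share 246 in each. Over 9362 genes of at least 5 CPM fold changes correlated at −0.210, with a covariance of −0.0449 (simulated −0.503 and −0.0144). Foxp3-deficient libraries spread the most, so −0.0144 may be too weak. Split into pairs, they gave 209 to 299 opposite calls over 6 assignments (median 238, median covariance −0.0253), above same-direction calls in 5. With replicates 3 and 5 in the first step and 1 and 4 in the second, 299 were opposite and 385 the same (covariance 0.0228). Against WT as shared control, 1148 genes changed in the same direction in both deficient groups (593 up, 555 down) and 28 in opposite directions. Independent lists would share 295 each way (simulations, again no baseline, gave 0). Fold changes correlated at 0.639 (simulated 0.497), with a covariance of 0.174 against 0.0141, and with WT libraries split 592 to 699 calls were shared in direction and 7 to 30 opposed.

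**Figure D4:**
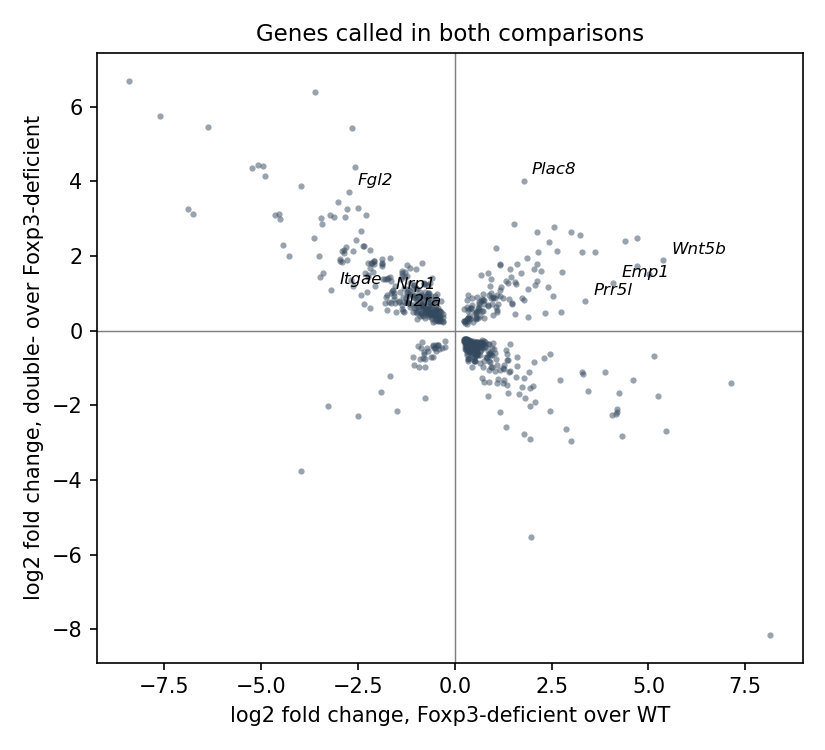
Log2 fold change of double-deficient over Foxp3-deficient cells (y axis) against that of Foxp3-deficient over WT cells (x axis) for genes called in both comparisons (points). Opposite signs were found for 491 genes and equal signs for 154.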

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

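The tests of class II genes and of clusters of genes switched on or off were chosen only after the result was seen, and so were leaving out groups with few reads and counting fewer than 20 genes as too few. In groups of 4 libraries, a library was set apart where its gap to the nearest other library took up most of the group's range (95% critical value of Dixon's ratio). This held for 36 of 619 groups tested (5.82%), over the genes named and depth and quality measures, and chance gives about 1 in 20 groups. Another 5 groups with at most 3 reads of a gene over 4 libraries were left out, because single reads against zeros fix the ratio. Foxp3-deficient libraries accounted for 19 of the 36, WT libraries for 11 and double-deficient libraries for 6.

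WT replicate 1 stood apart for Cd8b1 (21.1 CPM against 17.1 to 17.6, ratio 0.875) and Tnfsf8 (98 CPM against 109 to 111, ratio 0.886). WT replicate 3 stood apart for Ggt5 (0.62 CPM against 0.93 to 0.96, ratio 0.912) and Il12rb1 (47.4 CPM against 55.9 to 57.5, ratio 0.842). WT replicate 4 stood apart for Emp1 (2.94 CPM against 2.23 to 2.33, ratio 0.859), Ly6c1 (81.3 CPM against 102 to 103, ratio 0.932) and Rrm2 (21.4 CPM against 16.9 to 17.4, ratio 0.877). WT replicate 5 stood apart for Eif4ebp1 (11.6 CPM against 8.08 to 8.56, ratio 0.865), Ighg3 (2.15 CPM against 3.23 to 3.35, ratio 0.9), Mdh1 (390 CPM against 304 to 317, ratio 0.853) and Uqcrc2 (170 CPM against 145 to 147, ratio 0.907). Foxp3-deficient replicate 1 stood apart for Cyp51 (123.4 CPM against 87.4 to 89.6, ratio 0.939), Dapl1 (6.98 CPM against 12.8 to 13.4, ratio 0.902), Nr4a2 (12.9 CPM against 16 to 16.6, ratio 0.832), Pfkm (28 CPM against 18.1 to 19.5, ratio 0.857) and Pik3r5 (241 CPM against 201 to 208, ratio 0.837). Foxp3-deficient replicate 3 stood apart for Dusp2 (1025 CPM against 565 to 618, ratio 0.884), Egr1 (673 CPM against 272 to 325, ratio 0.869), Havcr2 (1.29 CPM against 0.15 to 0.3, ratio 0.868), Il17f (5.46 CPM against 0.49 to 1.24, ratio 0.849), Plac8 (11.9 CPM against 1.73 to 3.15, ratio 0.861), Tnfrsf9 (70.2 CPM against 95 to 98, ratio 0.891) and Zfp36 (1615 CPM against 697 to 846, ratio 0.837). Foxp3-deficient replicate 4 stood apart for Sdc4 (4.29 CPM against 1.78 to 2.17, ratio 0.845) and Slc2a3 (65.9 CPM against 75.7 to 77.5, ratio 0.851). Foxp3-deficient replicate 5 stood apart for Cxcr6 (139 CPM against 46.9 to 58.1, ratio 0.878), Icos (165 CPM against 97.5 to 109, ratio 0.832), Il12rb2 (6.55 CPM against 0.43 to 0.93, ratio 0.918), Klrg1 (27.2 CPM against 1.23 to 2.69, ratio 0.944) and Lta (44.4 CPM against 53.6 to 54.7, ratio 0.895). Double-deficient replicate 2 stood apart for Wdfy1 (8.37 CPM against 11.1 to 11.4, ratio 0.89). Double-deficient replicate 3 stood apart for Ccr4 (53.7 CPM against 44.8 to 45.5, ratio 0.922), Ifit1 (179 CPM against 121 to 129, ratio 0.858) and Stat4 (198 CPM against 175 to 178, ratio 0.857). Double-deficient replicate 5 stood apart for Epcam (15.1 CPM against 11.4 to 11.6, ratio 0.948) and Klrg1 (15.1 CPM against 5.36 to 6.65, ratio 0.868). The labels give no batch to set against these, so no explanation was tested.

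The OXPHOS nuclear and ribosomal protein genes were higher in double-deficient than in Foxp3-deficient cells, with median log2 fold changes above that of all genes of 0.54 and 0.68. A test under other scalings decided nothing, because rescaling moves all genes alike (lower medians 0.539 and 0.675). With each library's trend in length and GC content removed, 40.0% of the OXPHOS median was left (log2 0.22, interquartile range 0.12 to 0.43) and 55.6% of the ribosomal median (log2 0.38, −0.05 to 0.69). Bootstrap 95% intervals (34.9 to 54.0 and 47.5 to 70.2) resampled genes and leave out spread between libraries. Camera still passed (adjusted p = 6.90e-06 and 6.36e-06), but not with an estimated correlation (0.603 for both). A trend with length and GC content may therefore account for part of both shifts. Whether the rest follows genotype or another library difference cannot be told, because the trend runs between the groups.

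Zfr, on the same chromosome as Rictor, fell in double-deficient cells, which raises the possibility of a chromosome segment carried along with the targeted allele. Within 15 Mb of Rictor, 3 of 39 genes (Zfr, Capsl and Gm2093; 7.69%) were called with at least a 2-fold difference, against 4.72% elsewhere (odds ratio 1.68, 95% interval 0.331 to 5.35, two-sided Fisher exact p = 0.431), and on the rest of chromosome 15 the share was 15 of 439 (odds ratio 0.707, 0.390 to 1.19, p = 0.209). With 39 genes, an excess near Rictor could be neither shown nor ruled out. Of 16 genes at least 16-fold different in double-deficient cells from both other groups (13 higher and 3 lower, among them Plekhg1, Eno1b, Gcg, Gabrd, Plac8, Ifitm1 and Cntn5), 15 had a position and 2 of these lay within 5 Mb of another (permutation p = 0.458), too few genes to tell chromosome segments of another strain from single changes. A direct effect of Rictor loss on Zfr was not tested.

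B cell markers and Cd74 were higher in WT cells, where the excess of Cd74 over Foxp3-deficient cells was 89.8 CPM. The class II genes H2-Aa, H2-Ab1 and H2-Eb1, which antigen-presenting cells express with Cd74, together reached 1.58% of that excess in WT, and 5 myeloid and dendritic transcripts reached 0.726%. The condition set beforehand in favour of B cells was met: 6 of 6 B cell transcripts were lower in Foxp3-deficient cells, and they summed to 1400 CPM in WT (1560% of the excess). Ighm alone made up 1370 CPM of this sum, and it stood at 733 ± 69.7 CPM in Foxp3-deficient cells, where Cd74 stood at 11.3 CPM. Ms4a1 had 4 reads in WT. B cells would also bring class II transcripts, so that the class II levels argue against antigen-presenting cells, B cells included, as the source of the Cd74 excess, but not of the Ighm difference; the sort on CD4 and the reporter would remove such cells. A change in the T cells with genotype stays open as a hypothesis, as does a difference tied to the reporter, which the design does not separate from genotype.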

How the results depend on the processing

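Removing length and GC trends, alone or with the block, and leaving out Foxp3-deficient 1 and 3 together were chosen only after the result was seen. The others were planned. Of 80 counts of genes under other settings 75 stayed within 1.5 times their value and 5 were lower. Of 6327 values of named genes 5807 kept direction and side of the threshold, 490 were no longer past it, 20 came past it and 10 reversed; of 1391 values of lists these numbers were 1242, 75, 67 and 7, and of 112 of Foxp3 and Rictor 99, 11, 1 and 1. In double-deficient against Foxp3-deficient cells, 2382 genes were called with only the groups compared (fewer libraries), 1987 with the block and length and GC trends removed, and 2153 (without double-deficient replicate 5) to 4430 (without Foxp3-deficient replicate 3) with 1 library left out. The opposite-direction overlap was 299 with only the groups compared and 237.5 (median) with the shared libraries split. Both used fewer libraries, which need not account for the lower numbers. Rictor in Foxp3-deficient against WT cells was no longer past the test with upper quartile scaling (0.3284, adjusted p = 0.0645), the stricter filter (0.3318, 0.0649), limma-voom (0.3358, 0.0558) and only the groups compared (0.345, 0.0823), and lay between 0.2422 (without Foxp3-deficient replicate 4) and 0.4113 (without WT replicate 4) with 1 library left out. Foxp3 in double-deficient against Foxp3-deficient cells lay between −0.3276 (adjusted p = 0.0448, without Foxp3-deficient replicate 5) and −0.1119 (without replicate 1) with 1 library left out, and at −0.007096 (0.977) without both Foxp3-deficient 1 and 3. With length and GC trends removed, without and with the block, values in double-deficient against Foxp3-deficient cells were −0.111 and −0.1008 for Rictor (no longer past the test), and reversed for Stat3 (0.03445, 0.05576), Hk1 (0.08102, 0.1178), Pfkp (0.1114, 0.1527), mt-Nd1 (−0.07839, −0.0616) and the OXPHOS mitochondrial list (−0.1998, −0.2612). Against WT they reversed for mt-Cytb (−0.3574, −0.3838), the OXPHOS mitochondrial list (−0.3453, −0.3781) and, without the block, Rictor (0.2457, adjusted p = 0.0372). The setting removes what runs with length and GC content; further causes were not tested. The Tfh list reversed without Foxp3-deficient replicates 1 and 3 (0.2347 against WT; −0.5811 in double-deficient against Foxp3-deficient cells), and OXPHOS nuclear in Foxp3-deficient against WT cells ran from −0.2941 (without Foxp3-deficient replicate 3) to −0.004709 (without replicate 1, reversed in its test). The cause was not tested. Pairing by replicate number stays open. Same-number correlations (group means removed) were 0.303, 0.226, 0.00255 and 0.407 for WT and Foxp3-deficient (other numbers −0.449 to 0.346). They were −0.193, −0.0328 and 0.133 for WT and double-deficient and −0.142 to 0.181 for the deficient groups. With the block 1783, 2756 and 3494 genes were called. Depth limits genes with few reads, such as Il17a and Ppp1r14c.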

Other observations

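No test in this part was chosen after the result was seen. Whether other splits of the same 8 libraries into 4 and 4 call as many genes was tested for each comparison, each over 35 splits with the real one included. In Foxp3-deficient against WT cells 1 split, the real one, reached 1812 calls and the highest other split gave 1. In double-deficient against Foxp3-deficient cells 1 split reached 3585 and the highest other gave 0, and in double-deficient against WT cells 1 reached 4299 and the highest other gave 0. In each comparison the real split thus had the most calls, the strongest outcome that 35 splits allow. All other splits mix genotypes, so a genotype difference widens the spread within their groups and lowers their calls. The test therefore does not exclude chance, nor a difference between libraries that runs with genotype.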
